A study of Homo sapiens with 24 samples.

How the data were processed

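Human CD4+ memory T cells from blood were stimulated, cultured with TGFβ1 and an AHR inhibitor or agonist, and collected at 4 times, with 3 biological replicates in each of 8 groups. The labels do not say whether replicates came from separate donors, so p-values measure the spread between these samples, which may be partly technical. Per the labels' protocols, total RNA was made into 3′ libraries with a kit that reads from the poly(A) end, and sequenced on a NextSeq. The submitters' processing notes name FastQC 0.11.5, STAR 2.6.0, HTSeq, DESeq2, R 4.1.1 and the build hg38. The annotation, the counting settings and the handling of reads that match several places are not given in the sources used here, so genes that share reads with near-identical copies, overlap or lie antisense to each other are uncertain.

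The deposited values are a signal, gene counts divided by 1 size factor per library by the authors, in a single table of 28278 gene symbols and 24 libraries. All values were whole reads once multiplied by the library's factor (100% within a tolerance of 0.01), so the reads were recovered, with 993228 to 4501947 per library. The factors matched those recomputed by the median-ratio method within each time, to a relative difference of 6.4e-11, so the deposited values are comparable within a time. The ratio of deposited factors to factors over all 24 libraries ran from 0.698 to 1.53. Comparisons between times are therefore given on the deposited scale and with factors over all 24 libraries, a setting added after seeing the data. Mean normalized totals were 1792694 at 12 h and 3595571 at 72 h. The 11489 genes at 0 in all libraries include genes that every cell uses, so a gene at 0 is called listed at 0.

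Tests used log2(value + 1) and genes with at least 10 normalized counts in at least 3 libraries, which left 10770. Fold changes on this scale understate the change of low genes. limma 3.58.1 with a mean-variance trend was fitted in R 4.3.3 to all 24 libraries with a mean per group and 16 residual degrees of freedom. Moderated two-sided tests were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. The contrasts were agonist against inhibitor at each time and averaged over the times, the F test of its difference among times, its difference between 72 h and 12 h, and each later time against 12 h over both arms. The last 3 contrasts share the 12 h libraries. The table held normalized values, so limma was the main test and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. On those reads edgeR called 25 genes at 12 h, 33 at 24 h, 63 at 48 h and 95 at 72 h.

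Of 23 gene lists, 18 had at least 5 tested genes and entered camera with a preset correlation of 0.01, adjusted over 72 tests, and again with a correlation estimated from the data. The lists were AHR targets, AHR pathway components, B cell helper, Th17 and Th22, Th1 and cytotoxic, Th2, regulatory T cell, TGF-beta response, AP-1 family, interferon-stimulated, T cell activation, memory and quiescence, cell cycle, cholesterol synthesis, NRF2, hypoxia and glycolysis, and heat shock genes, and B cell markers. Markers of CD8 and gamma-delta T cells, NK cells, monocytes and dendritic cells, and red cells and platelets had too few tested genes and are given by gene. None of the 13 mitochondrial-encoded genes of a further list was among the symbols analysed here (0 of 13), so that list has no result.

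Genes were named by a rule. It took 12 genes of the AHR and helper programmes in every case. At each time it took up to 5 rises and 5 falls that passed with a mean of at least 20 normalized counts and the same sign in all 3 pairs of libraries that share a label code. It also took up to 4 members of each list by smallest p, and the leading genes of the averaged and time contrasts. XIST, Y-linked genes, receptor segments and HLA genes were left out of the ranked parts. A few genes that the rule takes are not reported here. Groups, the contrasts and list tests above, lists, this rule and all but 2 of the other settings tried were fixed before the data were examined. Some further checks were chosen after the results were seen, and are marked where they are given.

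The labels give each library 1 of 3 codes, which recur in all 8 groups, and the replicates are numbered 1 to 3 by code. The labels do not say what a code stands for. Deviations from the group means correlated between same-numbered libraries of both arms at 0.156 to 0.233 at 12 h, 0.172 to 0.339 at 48 h and 0.317 to 0.45 at 72 h, all over the limit of 0.1, so the numbers were taken to pair the libraries at these times. The pairing comes from this check and not from the labels. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 5.38 to 24.4, correlation of log2 values 0.864 to 0.955).

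The tests were tested on simulated data with 200 of 10770 genes changed, 100 by 2-fold and 100 by 4-fold. The changed genes were drawn from those with a mean of at least 20 normalized counts at that time. The recovery rates therefore do not cover lower genes. Libraries were drawn independently, without the pairing seen in the data. At 12 h 56% and 94% were recovered with 21 unchanged genes called, at 24 h 43% and 84% with 6, at 48 h 28% and 88% with 3, and at 72 h 38% and 81% with 7. The F test, with genes changed at 72 h alone, recovered 8% and 61% with 4 unchanged genes called. Where a group had 0 reads, the fold is a lower bound with a floor of 3 reads over the group. Where it had 1 to 3 reads, the ratio has an exact 95% interval. Both cover counting error only. Gene positions came from RefSeq on GRCh38.p14, which matched 26998 symbols (95.5%). Alternatives covered the pseudocount, the filter, the scaling, the replicate block, the spread estimate, the tool and libraries left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.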

Results

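Gene expression was measured by 3′ RNA-seq, which reads the ends of transcripts, in primary human CD4+ memory T cells from blood. The cells were stimulated with beads carrying antibodies to CD3 and CD28 and cultured with TGFβ1. One arm also received CH-223191, an inhibitor of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. The other arm received TCDD, an AHR agonist. Cells were collected after 12, 24, 48 and 72 h, which gave 8 groups of 3 biological replicates and 24 libraries in all. The libraries held 993228 to 4501947 reads assigned to genes, 65845058 in total. The shallowest was replicate 2 of the inhibitor arm at 12 h, and mean depth was 1.96 times higher at 72 h than at 12 h. No arm without an AHR ligand was analysed here, so each difference is agonist against inhibitor and does not say which compound moved a gene. Of 28278 genes in the table, 11489 were listed at 0 in all 24 libraries, PDCD1 among them. After a filter on low values, 10770 genes were tested.

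The first question was what AHR activity changed in the cells 12 h after stimulation. Of the AHR target genes tested, CYP1B1, AHRR and TIPARP rose. CYP1B1, a xenobiotic-metabolising cytochrome, went from 5.09 ± 4.30 normalized counts with the inhibitor to 133 ± 48.6 with the agonist (SD, n = 3). AHRR, the repressor that AHR itself induces, rose by 3.64 ± 0.68 (SE) on the log2 scale, and TIPARP, another feedback regulator, rose by 2.32 ± 0.51. ITGA1, an integrin chain of tissue-resident T cells, rose by 2.40 ± 0.44, RNF144A by 2.09 ± 0.44 and TRAF4 by 1.94 ± 0.40. SCD, a fatty acid desaturase, and AIM2, a sensor of cytosolic DNA, were the genes that fell, with log2 changes of -1.79 ± 0.33 and -1.16 ± 0.23. CYP1A1 had 0 reads over the inhibitor libraries and 6 over the agonist libraries and did not pass (limma adjusted p = 0.745).

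Of the 9 tested AHR target genes, 3 rose, 0 fell and the others did not pass at 12 h, with 5 rising when adjusted over the list alone. The list moved up against the other genes (camera adjusted p = 1.71e-09) and kept its call with an estimated correlation (adjusted p = 0.000607). The TGF-beta response list also moved up (camera adjusted p = 0.000423, and adjusted p = 0.00686 with an estimated correlation). Of its 12 genes, 1 rose, ITGA1, and 4 rose when adjusted over the list alone. The AP-1 family list moved down (camera adjusted p = 0.0273), but this call was lost with an estimated correlation (adjusted p = 0.366) and without inhibitor replicate 1, inhibitor replicate 2 or agonist replicate 3 of this time (adjusted p up to 0.311), and limma called 0 of its 15 genes. The B cell helper list, with genes of follicular and peripheral helper T cells, did not pass (camera adjusted p = 0.098). It passed lower with the replicate block (adjusted p = 0.033), but not with an estimated correlation and no block (adjusted p = 0.483).

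In all, 32 of 10770 genes passed at 12 h by limma with Benjamini-Hochberg adjustment, 30 higher and 2 lower with the agonist, and 50 passed with the replicate number as a block (44 higher and 6 lower). Without agonist replicate 1 the count was 18. A fit of the 6 libraries of this time alone called 0 genes, with 494 at an unadjusted p under 0.05. That is fewer than the share of 0.05 of the 10770 genes expected by chance. edgeR on the recovered reads of all libraries called 25. Of 9 named genes called at 12 h, CYP1B1 alone passed in every fit that left out 1 of the 6 libraries.

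The same comparison was made at 24 h. CYP1B1 stood at 0.368 ± 0.638 normalized counts with the inhibitor and 309.8 ± 159 with the agonist (SD, n = 3). ITGA1 rose by 3.81 ± 0.44 on the log2 scale, TIPARP by 3.59 ± 0.51 and RHOU by 3.47 ± 0.50. The falls included AIM2 at -1.52 ± 0.23, RGS16, a regulator of G-protein signalling, at -1.46 ± 0.31, and RNF125 at -1.39 ± 0.31.

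Of the 21 cholesterol synthesis genes tested, 1 fell at 24 h, and 3 fell when adjusted over the list alone. The list moved down (camera adjusted p = 3.8e-06, and adjusted p = 0.003 with an estimated correlation), with 19 of 21 members below 0. The AHR target list moved up again (camera adjusted p = 1.71e-12, and adjusted p = 0.000145 with an estimated correlation), with 3 of its 9 genes higher and 5 when adjusted over the list alone. T cell activation genes moved down as a list (camera adjusted p = 0.00218), a call lost with an estimated correlation (adjusted p = 0.181) and without inhibitor replicate 1 of this time (adjusted p = 0.185). None of its 19 genes passed, and 3 fell when adjusted over the list alone. With the replicate block 3 fell, although the libraries of 24 h missed the limit of the pairing check. The cell cycle list moved up at 24 h (camera adjusted p = 0.00485) and the AP-1 family (0.00673) and B cell helper lists (0.0426) moved down. These 3 calls were lost with an estimated correlation, at adjusted p = 0.366 for the cell cycle list, adjusted p = 0.26 for the AP-1 family and adjusted p = 0.366 for the B cell helper genes. They were also lost when single libraries were left out: the cell cycle call without inhibitor replicate 1 or agonist replicate 2 of 24 h (adjusted p up to 0.389), the AP-1 call without agonist replicate 3 of 24 h (0.107), and the B cell helper call without inhibitor replicate 1 or 3 or agonist replicate 2 of 24 h or inhibitor replicate 1 or 2 of 12 h (up to 0.402).

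At 24 h, 39 genes passed by limma, 32 higher and 7 lower with the agonist. With the replicate block, whose pairing check missed its limit at this time, 76 passed (57 higher and 19 lower). The count was 21 without agonist replicate 1 and 62 without inhibitor replicate 3, and a fit of the 6 libraries of this time alone called 1 gene. Of 13 named genes called at 24 h, 8 passed in every fit that left out 1 of the 6 libraries. The RNF125 call was lost without inhibitor replicate 2 or 3 or any agonist replicate (adjusted p up to 0.24), and the RGS16 call without inhibitor replicate 2 or 3 or agonist replicate 1 or 2 (up to 0.127).

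Genes lower with the agonist at 48 h included CXCL13, IL2, IL3, CD40LG and ICOS. CXCL13, the chemokine that attracts B cells, stood at 62.1 ± 19.1 normalized counts with the inhibitor and 7.14 ± 5.06 with the agonist (SD, n = 3), a ratio of 8.70. IL2, the T cell growth factor, fell from 31.3 to 2.67 mean normalized counts (log2 change -3.23 ± 0.52), and IL3 fell by 2.97 ± 0.55 on the log2 scale. CD40LG, the ligand through which T cells license B cells, stood at 1058 ± 303 and 299.9 ± 33.1 in the same order. ICOS, a co-stimulatory receptor, stood at 672 ± 108 and 405 ± 11.1. The chemokine receptor CCR1, RGS16 and AIM2 fell, with log2 changes of -2.28 ± 0.53, -2.17 ± 0.31 and -1.88 ± 0.23.

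CYP1B1, CYP1A1, STMND1, GJB6 and AHRR were higher with the agonist at 48 h. CYP1B1 stood at 3013 ± 864 normalized counts with the agonist against 1.95 ± 3.38 (SD, n = 3). CYP1A1 had 147 reads against 0, at least 49.9-fold higher with a floor of 3 reads over the group, and STMND1, with 126 against 0, was at least 43.8-fold higher. GJB6, which encodes a connexin of gap junctions, had 177 reads against 2, a ratio of 90.6 with a 95% counting interval of 24.7 to 754. AHRR rose by 5.66 ± 0.68 on the log2 scale.

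Of 23 B cell helper genes at 48 h, 4 fell, 1 rose and the others did not pass. When adjusted over the list alone, 8 fell and 2 rose, and with the replicate block 7 fell and 1 rose. CD40LG, CXCL13 and ICOS were among the falls, and TIGIT, an inhibitory receptor, rose by 2.10 ± 0.44. The list moved down (camera adjusted p = 2.82e-05), and with an estimated correlation it missed the threshold (adjusted p = 0.058). IL21, the helper cytokine, stood at -2.08 ± 0.56 and did not pass (limma adjusted p = 0.108), but passed with the replicate block (adjusted p = 0.00551). T cell activation genes moved down (camera adjusted p = 5.23e-13, and adjusted p = 0.00347 with an estimated correlation): 4 of 19 fell, including CD40LG, IL2 and CD44, and 10 fell when adjusted over the list alone. Memory and quiescence genes moved down (camera adjusted p = 0.00214, and adjusted p = 0.0174 with an estimated correlation), with 1 of 17 lower, BTG1, 4 lower and 1 higher when adjusted over the list alone, and 3 lower with the replicate block. Cholesterol synthesis genes moved down as a list (camera adjusted p = 0.00148, and adjusted p = 0.0215 with an estimated correlation) with 0 of 21 passing, 1 lower when adjusted over the list alone and 1 lower with the replicate block.

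The AHR target list moved up at 48 h (camera adjusted p = 2.52e-18, and adjusted p = 1.69e-05 with an estimated correlation), with 4 of 9 higher and 5 when adjusted over the list alone. AHR pathway components moved up (camera adjusted p = 0.000778, and adjusted p = 0.0228 with an estimated correlation), but AHRR was the 1 member of 7 that rose, with 2 when adjusted over the list alone. AHR itself did not pass at any of the 4 times, with log2 changes between -0.08 and 0.21. The remaining calls at 48 h were lost with an estimated correlation. They were Th2 genes lower (camera adjusted p = 0.000802, then adjusted p = 0.0926 with an estimated correlation), AP-1 family lower (0.00673, then adjusted p = 0.26), Th1 and cytotoxic genes lower (0.00973, then adjusted p = 0.366), hypoxia and glycolysis genes lower (0.0168, then adjusted p = 0.193) and TGF-beta response genes higher (0.0246, then adjusted p = 0.0647). Leaving out single libraries of 48 h also ended them: agonist replicate 1 for Th2 (adjusted p = 0.0569), hypoxia (0.0666) and TGF-beta response genes, inhibitor replicate 3 for the last list too (up to 0.146), and inhibitor replicate 1 or agonist replicate 2 for the AP-1 family (up to 0.102) and Th1 genes (up to 0.103). In these lists FOSL2, of the AP-1 family, fell by 0.95 ± 0.21 on the log2 scale and ITGA1 rose by 2.38 ± 0.44. IFNG stood at -1.59 ± 0.59 and did not pass (limma adjusted p = 0.467), but passed with the replicate block (adjusted p = 0.00108). The cell cycle list passed higher at 48 h with the block alone (adjusted p = 0.0465, against 0.0757 without it, and adjusted p = 0.569 with an estimated correlation and no block). The block also took the falls from 1 to 2 in the AP-1 and heat shock lists and from 0 to 1 in the Th1, Th2 and Th17 lists, and called 1 rise and 1 fall among hypoxia genes, where there were 0.

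At 48 h, 66 genes passed by limma, 32 higher and 34 lower, and 129 with the replicate block (53 higher and 76 lower). The count was 43 without inhibitor replicate 1, 36 without inhibitor replicate 3, 35 without agonist replicate 2 and 39 without agonist replicate 3. Of 25 named genes called at 48 h, 14 passed in every fit that left out 1 of the 6 libraries. The CXCL13 call was lost without inhibitor replicate 1, agonist replicate 2 or agonist replicate 3 (adjusted p up to 0.141). The ICOS, CCR1 and BTG1 calls were lost without any 1 of the 6 libraries (up to 0.356, 0.308 and 0.259). The FOSL2 call was lost without replicate 1 or 2 of the inhibitor or 2 or 3 of the agonist (up to 0.258), TIGIT without inhibitor replicate 3 or agonist replicate 1 or 3 (up to 0.195), and IL3 without inhibitor replicate 1 or agonist replicate 2 (up to 0.0639).

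**Figure D1:**
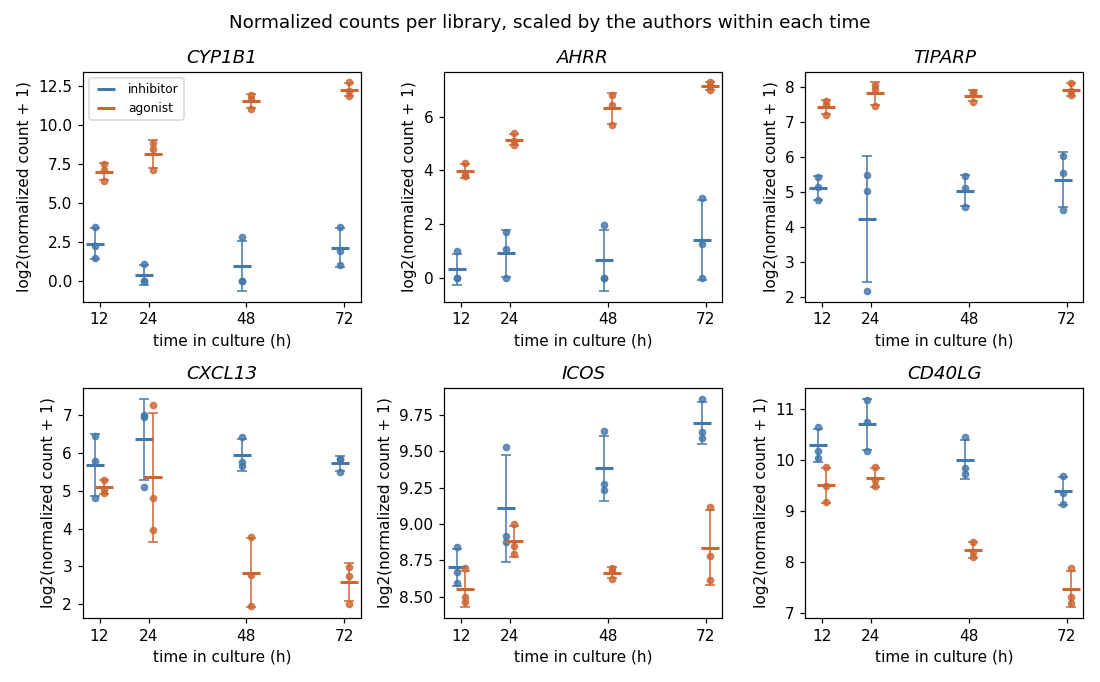
Normalized counts of CYP1B1, AHRR, TIPARP, CXCL13, ICOS and CD40LG, as log2(normalized count + 1), against time in culture in hours. Points are libraries (3 per arm and time), wide marks are means and bars are SD. The authors scaled libraries within each time, so arms are compared within a time. At 72 h all agonist libraries lie above all inhibitor libraries for CYP1B1, AHRR and TIPARP and below them for CXCL13, ICOS and CD40LG.

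At 72 h, the last time, CXCL13 stood at 52.0 ± 7.06 normalized counts with the inhibitor and 5.26 ± 2.0 with the agonist (SD, n = 3), a ratio of 9.88 and a log2 change of -3.13 ± 0.64 (limma adjusted p = 0.00906). ASCL2, a transcription factor of follicular helper cells, fell by 4.07 ± 0.65 on the log2 scale. The log2 changes were -1.93 ± 0.24 for CD40LG, -0.86 ± 0.17 for ICOS and -1.22 ± 0.26 for MAF, a transcription factor of helper cells. They were -4.48 ± 0.84 for ABCA1, a cholesterol exporter, -2.76 ± 0.55 for EFR3B and -2.45 ± 0.53 for GALR2. CYP1B1 stood at 4.55 ± 4.71 and 5057 ± 1552, a ratio of 1111, CYP1A1 was at least 76.7-fold and STMND1 at least 120-fold higher, and the connexin genes GJB2 and GJB6 rose by 6.12 ± 0.94 and 5.76 ± 0.95.

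Of the 23 B cell helper genes at 72 h, 5 fell, 1 rose and the others did not pass (8 lower and 2 higher when adjusted over the list alone, and 9 lower and 1 higher with the replicate block). The list moved down (camera adjusted p = 3.68e-08, and adjusted p = 0.017 with an estimated correlation), while TIGIT rose by 1.97 ± 0.44. T cell activation genes moved down (camera adjusted p = 1.25e-10, and adjusted p = 0.00722 with an estimated correlation). Of the 19, 3 fell, namely CD44, CD40LG and TNFRSF9, and 7 when adjusted over the list alone, as with the replicate block. Regulatory T cell genes moved down (camera adjusted p = 7.37e-05, and adjusted p = 0.00926 with an estimated correlation): TNFRSF9 fell, TIGIT rose, 7 of 14 fell and 1 rose when adjusted over the list alone, and 5 fell and 1 rose with the replicate block. FOXP3, the lineage factor of these cells, stood at -0.98 ± 0.29 and did not pass (limma adjusted p = 0.165). Memory and quiescence genes moved down (camera adjusted p = 0.00148, and adjusted p = 0.0164 with an estimated correlation), with 1 of 17 lower, the survival gene BCL2 at -1.12 ± 0.20, and 3 lower and 1 higher when adjusted over the list alone, as with the replicate block. The memory call was lost without agonist replicate 1 of this time (adjusted p = 0.0613).

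The AHR target list again moved up at 72 h (camera adjusted p = 1.36e-19, and adjusted p = 1.69e-05 with an estimated correlation), with 5 of 9 higher, and AHR pathway components moved up through AHRR (camera adjusted p = 0.00139, and adjusted p = 0.0298 with an estimated correlation). Interferon-stimulated genes moved up as a list (camera adjusted p = 0.00735), a call lost with an estimated correlation (adjusted p = 0.569) and without agonist replicate 2 of this time (adjusted p = 0.164). Of its 29 genes, 1 rose and 0 fell by limma, with the same counts when adjusted over the list alone. Th2 genes moved down (camera adjusted p = 0.000702, then adjusted p = 0.0889 with an estimated correlation), with IL13, a type 2 cytokine, lower by 3.26 ± 0.66 on the log2 scale. Th1 and cytotoxic genes moved down (camera adjusted p = 0.0054, then adjusted p = 0.345 with an estimated correlation), with TBX21, the Th1 lineage factor, at -1.31 ± 0.23. Hypoxia and glycolysis genes (0.00139) and the AP-1 family (0.023) moved down and lost their calls at adjusted p = 0.0695 and adjusted p = 0.353 with an estimated correlation. Without inhibitor replicate 1 of 72 h the Th1 call (adjusted p = 0.0839) and the AP-1 call were lost, the latter also without inhibitor replicate 2 or agonist replicate 3 (up to 0.3). IFNG, at -1.85 ± 0.59, passed with the replicate block alone (adjusted p = 0.000142), as did IL9 (0.0262) and IL10 (0.00409). The Th17 and Th22 list passed lower with the block alone (adjusted p = 0.027, against 0.0524 without it, and adjusted p = 0.51 with an estimated correlation and no block). The TGF-beta response list did not pass at 24 h (camera adjusted p = 0.267) or 72 h (0.366). The cholesterol synthesis list did not pass at 12 h (camera adjusted p = 0.546) or 72 h (0.859). JUN and IL22 did not pass at any time. The block took the falls from 1 to 2 in the Th1 and Th2 lists and from 0 to 1 among hypoxia genes.

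At 72 h, 96 genes passed by limma, 44 higher and 52 lower, and 177 with the replicate block (63 higher and 114 lower). The count was 55 without inhibitor replicate 1, 63 without agonist replicate 1 and 54 without agonist replicate 3. Of 32 named genes called at 72 h, 16 passed in every fit that left out 1 of the 6 libraries. The CXCL13, EFR3B and TNFRSF9 calls were lost without inhibitor replicate 1 or agonist replicate 3 (adjusted p up to 0.075, 0.075 and 0.0646), GALR2 without these or inhibitor replicate 2 (up to 0.178), and ICOS without replicate 1 of either arm (up to 0.081). The IL13 call was lost without inhibitor replicate 2 or agonist replicate 1 or 3 (up to 0.104), MAF without inhibitor replicate 1 or agonist replicate 2 or 3 (up to 0.148), and TIGIT without inhibitor replicate 3 or agonist replicate 1 or 2 (up to 0.249).

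**Figure D2:**
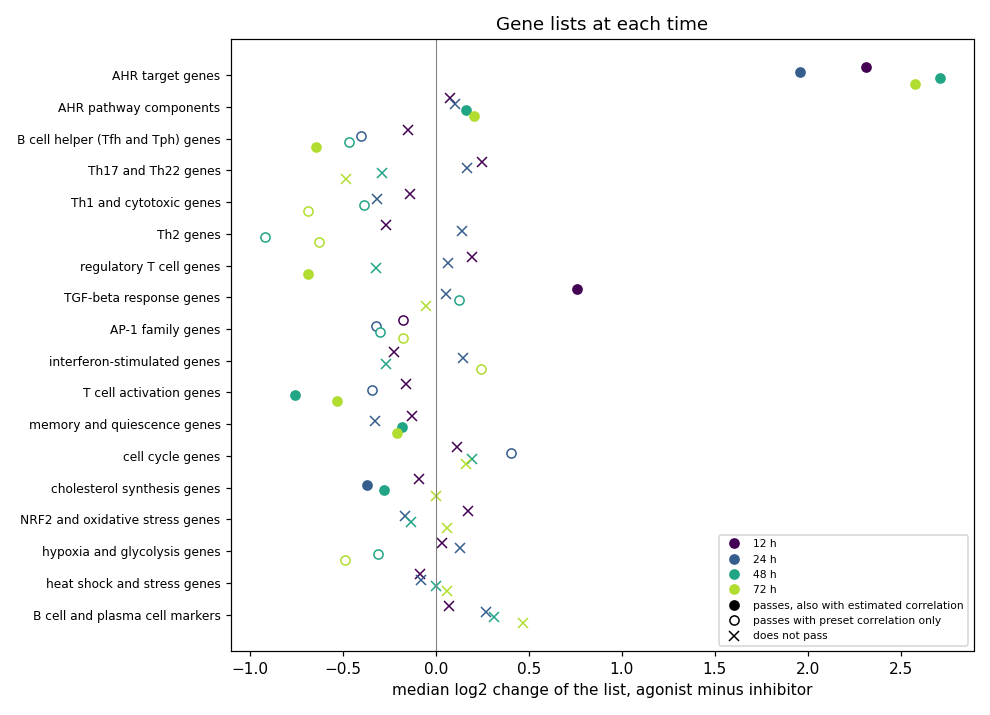
Median log2 change of each tested gene list, agonist minus inhibitor, at 12, 24, 48 and 72 h (colours). Filled circles passed camera with the preset and with an estimated correlation, open circles with the preset one alone, and crosses did not pass. AHR target genes lie between 1.96 and 2.71 at all 4 times, and T cell activation genes at -0.76 and -0.53 at 48 and 72 h.

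The 4 times were then set side by side. In all, 146 genes passed at 1 or more times and 12 at all 4, with the same sign, among them CYP1B1, AHRR, TIPARP, ITGA1, RHOU and AIM2. Of the 66 genes called at 48 h and 96 at 72 h, 45 were shared, all with the same sign (26 higher and 19 lower), against 0.131 and 0.164 expected for independent lists. The lists share 1 fit, its spread per gene and the label codes, so they are not independent and this is no test. Averaged over the 4 times, 382 genes passed by limma, 177 higher and 205 lower with the agonist. The averaged rises included those of CYP1B1 (8.28 ± 0.33), AHRR (4.81 ± 0.34), GJB6 (3.58 ± 0.47) and RHOU (3.58 ± 0.25), and the falls included ASCL2 (-2.15 ± 0.33), CXCL13 (-1.95 ± 0.32), IL13 (-1.84 ± 0.33) and IL3 (-1.73 ± 0.28). IL21 fell by 1.22 ± 0.28 (limma adjusted p = 0.0093). LYZ, a monocyte marker, rose by 2.51 ± 0.44 (adjusted p = 0.000594) at means of at most 10.6 normalized counts per group, while CST3, the other tested monocyte marker, did not pass (adjusted p = 0.939). The NRF2 and oxidative stress list (lowest camera adjusted p = 0.0757), the heat shock and stress list (0.4) and the B cell and plasma cell markers (0.407) passed at no time. Of the lists with too few tested genes for camera, CD8A, the NK cell markers KLRD1, TYROBP and FCER1G, and the globin genes HBB and HBA2 passed at no time, with a lowest limma adjusted p of 0.262, for HBA2. Median, mean and test differed in sign for 9 list tests, of which 0 passed by camera. Without 48 h the averaged count was 207 and without 72 h it was 217, both added after seeing the data.

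Whether the agonist effect itself differed between times was tested directly. By the limma F test over the 4 times, 3 genes passed: STMND1 (adjusted p = 0.000173), CYP1B1 (0.0119) and CYP1A1 (0.0424), all with larger rises at 48 and 72 h than at 12 h. Between 72 h and 12 h the effect differed for 5 genes, higher for STMND1, CYP1B1 and CYP1A1 and lower for CD44 (-1.23 ± 0.22) and the cytokine receptor IL6R (-1.30 ± 0.25). IL6R was chosen after its values were seen. CXCL13 and ICOS passed at 48 and 72 h and not at 12 or 24 h, but their effects were not among these calls. In the main limma fit 453 genes (F test) and 511 genes (72 h minus 12 h) had an unadjusted p under 0.05. Both are fewer than the share of 0.05 of the 10770 genes expected by chance. edgeR on recovered reads called 0 genes in either test, with 432 and 546 at an unadjusted p under 0.05. The replicate block gave 6 and 16 genes. Without all libraries of number 1, of number 2 or of number 3, limma called 0 genes in either test, with 347 to 431 and 368 to 536 at an unadjusted p under 0.05. Single left-out libraries moved the F count to 1 (inhibitor replicate 1, agonist replicate 2 or agonist replicate 3 of 12 h) or 5 (inhibitor replicate 1 of 24 h), and the second count to between 1 and 3 without inhibitor replicate 2, agonist replicate 1 or agonist replicate 3 of 12 h, inhibitor replicate 1 or 3 of 72 h, or any agonist replicate of 72 h.

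Last, the time course was followed across both arms. Cell cycle genes rose and interferon-stimulated genes fell. With size factors computed over all 24 libraries, MKI67, a proliferation marker, went from 5.81 ± 4.17 at 12 h to 1448 ± 166 at 72 h (SD, n = 6), and RRM2, a subunit of ribonucleotide reductase, from 3.59 ± 4.34 to 1016 ± 103. The log2 changes of genes that fell included -8.03 ± 0.35 for IL2, -6.86 ± 0.53 for CXCL11, an interferon-induced chemokine, -5.80 ± 0.70 for IL22 and -5.76 ± 0.45 for IL13. All 26 cell cycle genes were higher at 72 h (median log2 change 5.49), all 29 interferon-stimulated genes were lower (median -2.48), and so were 15 of 19 T cell activation genes, with 3 higher, and 15 of 17 memory and quiescence genes. These lists kept their camera calls with an estimated correlation, at adjusted p = 0.00127, adjusted p = 0.0362, adjusted p = 0.0099 and adjusted p = 9.95e-05. A further 6 lists passed camera and lost the call with an estimated correlation. Of 19 hypoxia and glycolysis genes 12 were higher and 2 lower (camera adjusted p = 0.00973, then adjusted p = 0.132 with an estimated correlation). The other lists were lower. Of 23 B cell helper genes 10 were lower and 2 higher (0.0197, then adjusted p = 0.25), of 18 Th1 genes 7 and 1 (0.0197, then adjusted p = 0.343) and of 9 Th2 genes 6 and 1 (0.00973, then adjusted p = 0.194). Of 15 AP-1 genes 9 were lower and 2 higher (0.0101, then adjusted p = 0.244), and of 16 heat shock genes 9 and 2 (0.0197, then adjusted p = 0.0536).

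The deposited values were scaled within each time, and on them the median gene rose by 1.15 log2 between 12 h and 72 h, against 0.08 with size factors over all 24 libraries. On the deposited scale 8330 genes passed by limma at 72 h against 12 h, 7926 higher and 404 lower, and with the common size factors 4962, 2688 higher and 2274 lower. At 24 h the counts were 5184 (5080 higher and 104 lower) and 1721 (915 and 806), and at 48 h 6808 (6304 and 504) and 4301 (2341 and 1960). On the deposited scale the interferon-stimulated genes had 26 of 29 lower and the memory and quiescence genes 5 lower and 4 higher. The majority turned for B cell helper genes (3 lower and 12 higher), Th1 genes (3 and 6), AP-1 genes (3 and 8) and heat shock genes (3 and 10).

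**Figure D3:**
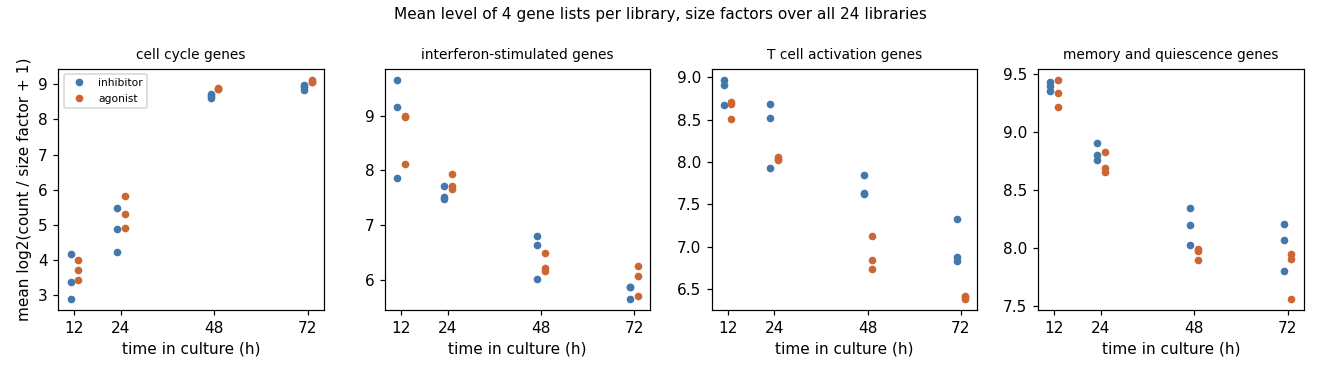
Mean level of the tested genes of 4 lists per library, as mean log2(count / size factor + 1) with size factors over all 24 libraries, against time in culture in hours. Points are libraries, 3 per arm and time. The cell cycle list is higher and the other lists are lower in every 72 h library than in every 12 h library.

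Positions are those of RefSeq on GRCh38.p14, the assembly family of the hg38 build in the submitters' processing notes. CYP1B1 spans 38067509 to 38076151 on chromosome 2, AHRR 321714 to 438285 on chromosome 5, CXCL13 77511753 to 77611834 on chromosome 4, ICOS 203936763 to 203961577 on chromosome 2 and STMND1 17102050 to 17131378 on chromosome 6. The 3′ reads fall near transcript ends, and the table gives 1 value per gene.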

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

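The counts over splits with the average agonist effect removed were chosen after the results were seen, and the interaction tests and the other splits were planned. The agonist effect differed among the 4 times by the limma F test for STMND1 (adjusted p = 0.000173), CYP1B1 (adjusted p = 0.0119) and CYP1A1 (adjusted p = 0.0424). Between 72 h and 12 h the effect was larger by 6.91 log2 for STMND1, 5.51 for CYP1B1 and 5.16 for CYP1A1. It was lower by the same contrast for CD44 (-1.23) and IL6R (-1.30), the latter chosen after its values were seen. STMND1 had 0 reads in both arms at 12 and 24 h, and CYP1A1 had 0 reads with the inhibitor at 12 and 72 h, so their differences depend on the pseudocount.

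For the F test, 4 of 100 drawn splits of the arms within each time gave as many genes, the real one included (3 genes, highest other 24), and for 72 h minus 12 h 1 of 100 did (5 genes, highest other 2). These splits pass part of the average agonist effect to the difference between times, so they decide nothing for either test. With the average effect of each gene removed in equal parts from both arms, 3 of 100 splits gave as many for the F test (3 genes, highest other 30) and 1 of 100 for 72 h minus 12 h (5 genes, highest other 4). With all of it removed from the agonist arm, the values were 11 of 100 (1 gene, highest other 29) and 2 of 100 (3 genes, highest other 4). For 72 h minus 12 h the share of splits was under 0.05 in both forms, and for the F test in the first form alone. The average effect came from these same data with the real arms, and the splits leave the pairing by replicate number aside. edgeR on the recovered reads called 0 genes for 72 h minus 12 h. Chance is therefore excluded for neither test. For the F test, a split with several times the real count may reflect a structure of the samples, whose cause was not tested.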

How the results depend on the processing

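The settings with size factors over all 24 libraries and the averages without 1 time were chosen after seeing the data; the others were planned, and all of those ran. No agonist against inhibitor call of a named gene or list reversed. Between times directions did turn with the scaling, for example in B cell helper genes at 72 h, and with quantile normalization falls outnumbered rises at 48 h and 72 h against 12 h. Of 105 calls of named genes, quantile normalization kept 105, the replicate block 105 (with 29 gained), edgeR 100, DESeq2 103, no filter 96 and limma without the trend 82, and a fit of the 6 libraries of 1 time kept 44 of 79. Depth limits low genes, since 10770 of 28278 were tested. The cause of the moves below was not tested. Fits of 6 libraries have fewer residual degrees of freedom and take the spread of 1 time. The first alone does not account for their higher counts at 48 h and, with the replicate block, at 72 h.

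With the replicate block, where numbers pair the libraries, counts were 50 at 12 h, 129 at 48 h and 177 at 72 h, against 32, 66 and 96. At 24 h the libraries carry the same label codes but missed the limit of the pairing check (lowest correlation 0.0555), and as a hint from the data the block gave 76 genes against 39, with each of 3 libraries closest to its own number. The block gave 6 genes for the F test and 16 for 72 h minus 12 h. For the averaged effect it gave 533, within 1.5 times of 382, and it gained 6 list calls and lost 0. At 24 h these were Th1 and memory genes lower and Th17 genes higher, at adjusted p = 0.505, adjusted p = 0.294 and adjusted p = 0.569 with an estimated correlation and no block. edgeR with the replicate block gave 78 at 24 h, 135 at 48 h, 181 at 72 h, 9 for 72 h minus 12 h, 1977 for 24 h, 4510 for 48 h and 5196 for 72 h against 12 h. A fit of 6 libraries with the replicate block gave 0 genes at 12 h (706 at an unadjusted p under 0.05), 0 at 24 h (574), 236 at 48 h and 566 at 72 h by limma.

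A fit of the 6 libraries alone gave 0 at 12 h (494 at an unadjusted p under 0.05), 1 at 24 h and 107 at 48 h by limma. DESeq2 gave 85 at 24 h, 112 at 48 h, 161 at 72 h and 17 for the F test. limma without the trend gave 43 at 48 h and 3 for 72 h minus 12 h. The averaged effect had 207 genes without 48 h and 217 without 72 h. The F test called 1 gene with pseudocount 0.5, 6 with pseudocount 5, 12 with no filter, 1 with the mean of 50 filter and 0 with edgeR (432 at an unadjusted p under 0.05). For 72 h minus 12 h the counts were 2 with pseudocount 0.5, 13 with no filter, 3 with the mean of 50 filter, 3 with the same total per library and 0 with edgeR (546 at an unadjusted p under 0.05).

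Quantile normalization gave 1606 genes at 24 h (918 higher and 688 lower), 4282 at 48 h (2077 and 2205) and 4962 at 72 h (2368 and 2594) against 12 h. The same total per library gave 1811 (1260 and 551), 4465 (2887 and 1578) and 5025 (3112 and 1913). Size factors over all 24 libraries gave 1721, 4301 and 4962, edgeR 1629, 4152 and 4912, and DESeq2 1992, 4455 and 5153. Of 72 list tests 31 passed, against 15 with an estimated correlation and 19 with the self-contained test fry, which does not compare a list with other genes.

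Leaving out 1 library, or all libraries of 1 number, gave 0 to 31 genes at 12 h, 7 to 62 at 24 h, 10 to 48 at 48 h, 10 to 70 at 72 h and 145 to 420 for the averaged effect. The range was 0 to 5 for the F test, 0 to 6 for 72 h minus 12 h, 3839 to 5286, 5594 to 6623 and 7539 to 8195 for 24, 48 and 72 h against 12 h, and 25 to 38 for list tests. The lowest values came without all libraries of number 1 (12 h, 24 h and the time contrasts) or number 3 (48 h, 72 h, averaged effect and lists). Without each of the numbers the F test and 72 h minus 12 h called 0 genes by limma (347 to 431 and 368 to 536 at an unadjusted p under 0.05).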

Other observations

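The tests of the MHC interval and the ubiquitous genes, of the scaling and depth behind the excess of rises, of the time course among genes called at 72 h, and of time splits with size factors over all 24 libraries were chosen after the results were seen. Averaged over the 4 times, 9 of 19 T cell activation genes were lower with the agonist by limma and 6 of 9 AHR target genes were higher. Of 23 B cell helper genes 8 were lower and 2 higher. The activation list kept its camera call with an estimated correlation (adjusted p = 0.00855), as did the helper list (adjusted p = 0.0236) and the TGF-beta response list (adjusted p = 0.0236), whose 2 passing genes of 12 rose. The list of 26 cell cycle genes stood above the other genes in the averaged effect (camera adjusted p = 0.00185, then adjusted p = 0.212 with an estimated correlation).

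Many genes were listed at 0 in all 24 libraries, among them genes of the MHC, which lies between 29672392 and 33409896 on chromosome 6. Of 140 protein-coding genes there 106 were at 0, 75.7% (exact 95% interval 67.8 to 82.6), against 25.2% on the rest of the chromosome (Fisher exact p = 3.1e-30), and RPS18 had 8 reads where the median ribosomal protein gene had 98087. From PLEKHM1 to NSF on chromosome 17, a locus with a second haplotype, 63.6% of 11 genes were at 0 against 26.4% (Fisher exact p = 0.011). These genes are not independent, since STH lies within MAPT and LINC02210-CRHR1 overlaps CRHR1. Which of them these cells express was not tested. Reads lost where the reference holds alternate haplotypes may account for part of the zeros. Of 20 ubiquitous MHC genes 15 held at most 3 reads, but this list was written after the zeros were seen, so low expression cannot be told apart for the genes as a set. No biological explanation was tested.

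On the deposited scale the median gene rose between 12 h and 72 h, and with size factors over all 24 libraries its log2 change was 0.0831. Mean reads per library were 1.96 times higher at 72 h, close to the ratio of mean normalized totals (2.01). Neither value is a test, since both follow from how the values were scaled. Factors over all 24 libraries place the median gene near 0 whatever the cause. Scaling within each time leaves depth in the values, so the normalized totals follow the reads. Deposited factors had a median 0.601 log2 above the common ones at 12 h and 0.506 below at 72 h. The excess of rises on the deposited scale therefore carries this difference in depth and says nothing about RNA per cell. Why depth differed, and whether total RNA per cell changed, was not tested.

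More genes were called at 72 h than at 12 h (96 and 32), but at an unadjusted p under 0.05 the order was the opposite (645 and 849). After thinning every library to 993228 reads, the ratio of the counts was at least 5.44 in 5 thinnings, which argues against depth as the whole cause. After the same thinning, the median SD within groups was not larger at 12 h (ratio to 72 h at most 0.964). This argues against a larger spread at 12 h at that common depth. Before thinning, log2 values of replicates correlated at 0.9 to 0.926 at 12 h and at 0.925 to 0.953 at 72 h. Fits of the 6 libraries of each time alone take the spread of that time. Against the main fit, their unadjusted counts fell at 12 h (849 to 494) and 24 h (1037 to 523). They rose at 48 h (641 to 1050) and 72 h (645 to 908), with equal residual degrees of freedom at each time. This argues for a larger spread at 12 and 24 h than later in the values tested. In these fits the order of 12 h and 72 h turned. Whether the effect grew with time stays open. The order of the unadjusted counts depends on the fit, the F test called 3 genes and other causes were not tested.

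As a hypothesis, cells with the agonist may have been further along the time course. In the inhibitor arm, whose 12 and 48 h libraries are not part of the comparison at 72 h, 23 of the genes lower with the agonist at 72 h were lower and 3 higher at 48 h against 12 h. Of the genes higher with it 12 were lower and 7 higher (odds ratio 4.32, Fisher exact p = 0.0698). The genes are too few to decide and are not independent replicates, so the hypothesis stays open.

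Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 32 genes at 12 h (highest other 4), 39 at 24 h (8), 66 at 48 h (0, by limma) and 96 at 72 h (0, by limma). For the averaged effect 1 of 100 splits, the real one, gave as many genes (382, highest other 216), a share under 0.05. This concerns the number of genes and not each gene, and the splits leave the pairing by replicate number aside. For the list tests 1 of 100 splits, the real one, also gave as many calls (31, highest other 26). The 31 calls include the 4 AHR target calls. Since another split gave 26 calls, the test says nothing about any other single list. Against 12 h, the real split alone of 100 gave as many genes with size factors over all 24 libraries, a share under 0.05. This held at 24 h (1721, highest other 704), 48 h (4301 and 1840) and 72 h (4962 and 2849). On the deposited scale it also did (5184 and 2309, 6808 and 3764, 8330 and 5590), but there the scaling within each time separates the times too.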
